A study of Homo sapiens with 12 samples.

How the data were processed

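Primary human corneal and cervical epithelial cells, bought from a supplier per the labels' protocols, were treated with DMSO, NEDD8i or SUMOi. The treatment protocol gives 16 h for DMSO or NEDD8i, and the time for SUMOi is not given in the sources used here. The sample names also carry the term D3, whose meaning is not given in the sources used here. All 12 samples have the tissue label cornea, and the cell type was taken from the sample names. Per the labels' protocols, RNA was made into libraries with a QuantSeq 3' mRNA kit (forward), which reads the 3' end of polyadenylated transcripts, and sequenced paired-end. Each of the 6 groups (2 cell types by 3 treatments) held 2 libraries. The labels do not say what a replicate number stands for.

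The deposited values are counts, raw numbers of reads per gene and library, whole numbers whose totals differ between libraries. Per the file headers, the authors counted reads with featureCounts 2.0.6 on the annotated strand (strand option 1), over exons summed by gene, with the basic annotation of GENCODE 39. The command holds no option for multi-mapping reads or for paired fragments and was run on 55 alignment files, of which 12 are columns here. The alignment files came from a folder named filter, and what was filtered is not given in the sources used here. Per the submitters' processing notes, reads were aligned with STAR to GRCh38 and DESeq2 was used downstream, with versions not given in the sources used here. Reads shared between close paralogs are lost or misassigned by such counting, which concerns AKR1C1, LCE3D, SPRR2E, S100A7, KRT14 and KRT17 among the genes named.

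Positions and gene identifiers are those of the counts table. Of its 61533 genes, 61415 identifiers were named from a reference table of gene names, 105 from GENCODE 29 and 13 kept no symbol. Left out of every result were 570 genes of chromosome Y and of X inactivation, since the samples come from people. No library was left out. Total counts per library differed by up to 4.418-fold, and the floor for a gene without reads was set at 3 counts. Where a group held no read for a gene, the fold is a bound, computed with 3 counts over the whole group. A gene with 1 to 3 reads in a group is given by its level instead of a fold.

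Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were filtered with filterByExpr by group at its default settings, which left 15255 genes, and scaled with TMM. A quasi-likelihood F test with robust estimates was used, with 1 coefficient per group in 1 fit of all 12 libraries (6 residual degrees of freedom), so that all groups share the estimate of the spread. The common dispersion was 0.0448 (biological coefficient of variation 21.17%) and the median prior degrees of freedom 5.359. The prior count of fitted fold changes was 0.125. The standard error was taken as the absolute log2 fold change over the square root of F. P-values were two-sided and adjusted by Benjamini-Hochberg over all genes tested within each comparison, with a threshold of 0.05. The comparisons were each inhibitor against DMSO in each cell type, NEDD8i against SUMOi in each cell type, the interaction of each inhibitor with cell type, and corneal against cervical cells with DMSO. Shared calls were counted per direction beside the number that chance gives, the product of both counts over the genes tested. Both inhibitors share DMSO libraries, so 20 simulations of unchanged groups against the same controls gave the counts and covariances that arise without any change. No exact permutation test was used, because groups of 2 do not allow a small p, and other splits of groups of 2 were not counted for the same reason.

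Gene lists for pathways, cell types and RNA quality numbered 32, of which 30 had at least 5 tested members. The lists of immune cell and melanocyte markers had fewer and were not tested. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison. Named genes followed a rule. For each inhibitor comparison the 8 largest rises and 8 largest falls were eligible among called genes with a mean of at least 5 CPM and no overlap between the libraries of both groups. Up to 3 called members per direction of each list were eligible as well, or the member with the highest level where none was called. For NEDD8i against SUMOi and the interactions the 5 largest per direction were eligible, and for corneal against cervical cells the 8 largest. Genes without a symbol, pseudogenes, antisense and long noncoding names were excluded, and NEDD8 and SUMO genes could always be named. The text names a part of the eligible genes, and some withheld ones are not reported. Interaction values are given as well for every gene named in an inhibitor comparison whose interaction was called.

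The procedure was tested on simulated data with 200 changed genes per comparison. It found 18% to 28% of 2-fold and 78% to 86% of 4-fold changes for an inhibitor against DMSO, and 8% and 46% for the NEDD8i interaction. Of all calls, 3.48% to 8.57% were false. These rates may not hold at the unequal spread of these cell types. Pearson correlation between the replicates of a group, on log CPM across genes, was 0.964 to 0.97 in corneal and 0.989 to 0.993 in cervical groups.

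Alternatives were DESeq2 1.42.0 with its own size factors, edgeR with DESeq2 size factors, no count filter, a filter of at least 1 CPM in 4 libraries, replicate number within each cell type as a block, a separate fit per cell type, and each library left out in turn. For the lists they were a correlation estimated per list, fry, the block and each library left out. Total-count scaling, libraries thinned to 7286021 reads and the separate fit for lists were added after the data were seen. A count was taken as unchanged within 1.5 times the value reported. Figures were drawn with Python 3.11.15 and matplotlib.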

Results

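The series measured messenger RNA by sequencing of transcript 3' ends in primary human epithelial cells of the cornea and of the cervix. Cells of each type received the vehicle DMSO, NEDD8i or SUMOi, read here as inhibitors of the conjugation of NEDD8 and SUMO, the ubiquitin-like proteins in the series' title. Each of the 6 groups held 2 libraries, numbered as replicates, and the labels do not say whether these are separate donors or cultures. Total counts, in units of 1e+06 reads, were 15.26 and 11.39 for corneal DMSO, 27.72 and 7.288 for corneal NEDD8i, and 12.46 and 13.07 for corneal SUMOi. The cervical totals were 26.56 and 32.2 for DMSO, 16.03 and 11.36 for NEDD8i, and 15.97 and 13.18 for SUMOi. CPM are counts per 1e+06 after TMM scaling. Before it, the floor of 3 counts for a gene without reads was 0.0932 CPM in the deepest and 0.412 in the shallowest library. Floors and lower bounds cover counting error only. All 15255 genes that passed the count filter were tested with edgeR in 1 fit of the 12 libraries, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05. These p-values measure the spread between these libraries, which may be technical. Errors on log2 fold changes are standard errors of that fit, and errors on CPM are standard deviations over the 2 libraries of a group. Positions are on GRCh38.

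**Figure D1:**
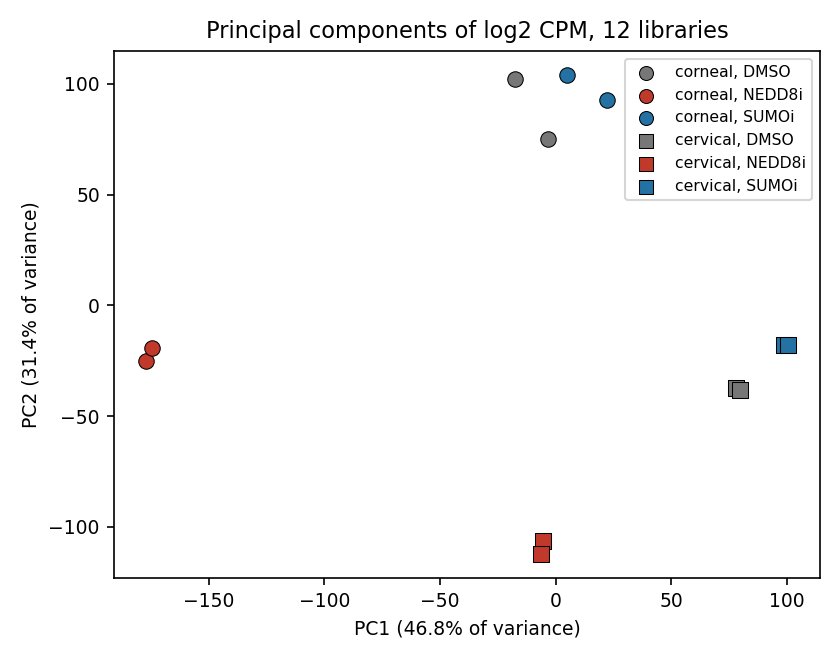
Principal components of the log2 CPM values of the 12 libraries, 1 point per library, with the share of variance on each axis (46.82% on the first, 31.45% on the second). On the first component the corneal NEDD8i libraries sat at -177 and -174.5 and the cervical NEDD8i libraries at -5.58 and -6.23.

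The first question was what NEDD8i changed in corneal cells. Of 29 NRF2 targets, the antioxidant genes, 22 rose, and of 40 genes of G2/M and mitosis 37 fell (adjusted p = 0.289 with an estimated correlation for both lists). TXNRD1 (thioredoxin reductase, ENSG00000198431.17, chromosome 12, 104215779 to 104350307) rose 24.3-fold (38.03 without DMSO replicate 1), from 96.5 ± 48.7 to 2346 ± 1030 CPM (n = 2 and 2 libraries). HMOX1 (heme oxygenase, ENSG00000100292.18, chromosome 22, 35381096 to 35394207) rose 71.4-fold, with a log2 fold change of 6.16 ± 0.59. UBE2C, a ubiquitin-conjugating enzyme of the anaphase-promoting complex, was 218-fold lower (-7.77 ± 0.55 on the log2 scale, and -12.33 without NEDD8i replicate 1, against 0 reads and so no bound). TP63, the transcription factor of basal epithelial cells (ENSG00000073282.14, chromosome 3, 189631389 to 189897276), was 46.8-fold lower (25.6 and 79.7 without NEDD8i replicates 1 and 2), while CDSN, the adhesion protein corneodesmosin of the outer epidermis, rose 54.4-fold. The edgeR adjusted p was 1.86e-05 for TXNRD1, 3.37e-05 for HMOX1, 2.14e-06 for UBE2C, 1.78e-06 for TP63 and 0.000762 for CDSN. In all, 7879 genes (51.65%) were called, 3887 higher and 3992 lower.

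Among the genes with the largest changes in corneal cells, 3 had no read in either DMSO library. TRH, the precursor of thyrotropin-releasing hormone, was at least 180-fold higher, ESM1, a secreted proteoglycan, at least 141-fold higher, and the toll-like receptor TLR10 at least 121-fold higher. MXRA5, a matrix protein, was at least 171-fold lower and the mitotic kinase NEK2 at least 102-fold lower, each without a read in the NEDD8i libraries. The bound was 118 for TRH without NEDD8i replicate 1, 69.7 for MXRA5 and 65.7 for NEK2 without DMSO replicate 2, and 272 for MXRA5 without DMSO replicate 1. For these 5 genes the edgeR adjusted p ran from 6.16e-06 for ESM1 to 0.000639 for MXRA5.

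The gene lists used here were fixed before the data were examined, and each was tested against all other genes with camera at a preset correlation of 0.01. Of 29 NRF2 targets, the antioxidant list, 22 rose in corneal cells, 1 fell and 6 were not called. The count was 22 rising and 2 falling adjusted over the list alone (camera adjusted p = 1.89e-07, and adjusted p = 0.289 with an estimated correlation). AKR1C1, an aldo-keto reductase with close paralogs, rose 19.2-fold, and the carbonyl reductase CBR1 fell 2.45-fold. Of 40 genes of G2/M and mitosis, 37 fell and 3 were not called, with 37 adjusted over the list alone (camera adjusted p = 2.41e-22, and adjusted p = 0.289 with an estimated correlation). The mitotic kinase CDK1 was 100.5-fold lower (57.9 without DMSO replicate 2, and 40.1 and 195 without NEDD8i replicates 1 and 2). Of 38 genes of G1/S and replication, 23 fell, 4 rose and 11 were not called, with 26 falling and 4 rising adjusted over the list alone (camera adjusted p = 4.14e-06, and adjusted p = 0.289 with an estimated correlation). TYMS, the thymidylate synthase, was 41.5-fold lower and the ribonucleotide reductase subunit RRM2 61.2-fold lower (-5.94 on the log2 scale, -3.86 without NEDD8i replicate 1 and -10.72, against 0 reads, without replicate 2), while the transcription factors E2F2 and E2F7 rose 7.03-fold and 4.69-fold. The largest edgeR adjusted p among the genes of this paragraph was 0.000271, for CBR1.

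Camera called the basal list lower and the differentiation list higher in the same cells. Of 24 basal epithelial genes, 15 fell, 3 rose and 6 were not called, as they did adjusted over the list alone (camera adjusted p = 1.09e-05, and adjusted p = 0.289 with an estimated correlation). DLK2, a membrane protein without a read under NEDD8i, was at least 27.6-fold lower, whereas the keratins KRT15 and KRT17 of the same list rose 3.76-fold and 2.49-fold. Of 50 genes of squamous differentiation, 33 rose, 3 fell and 14 were not called, with 33 and 3 adjusted over the list alone (camera adjusted p = 2.16e-08, and adjusted p = 0.529 with an estimated correlation). LCE3D, a late cornified envelope protein with close paralogs, rose 168-fold (95.5 and 568 without DMSO replicates 1 and 2) and the skin protease KLK6 rose 29.4-fold, while the calmodulin-like CALML3 fell 5.43-fold (3.01 without DMSO replicate 2). Of 31 junction genes, 17 rose, 3 fell and 11 were not called, with 21 and 3 adjusted over the list alone (camera adjusted p = 0.00252, and adjusted p = 0.289 with an estimated correlation). The tight junction protein TJP3 rose 11.2-fold and the connexin GJB2 fell 7.49-fold (4.48 and 24.7 without NEDD8i replicates 1 and 2). Without corneal NEDD8i replicate 2 the junction list missed the threshold (camera adjusted p = 0.0549). The edgeR adjusted p of the named genes was at most 0.00443, for GJB2.

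**Figure D2:**
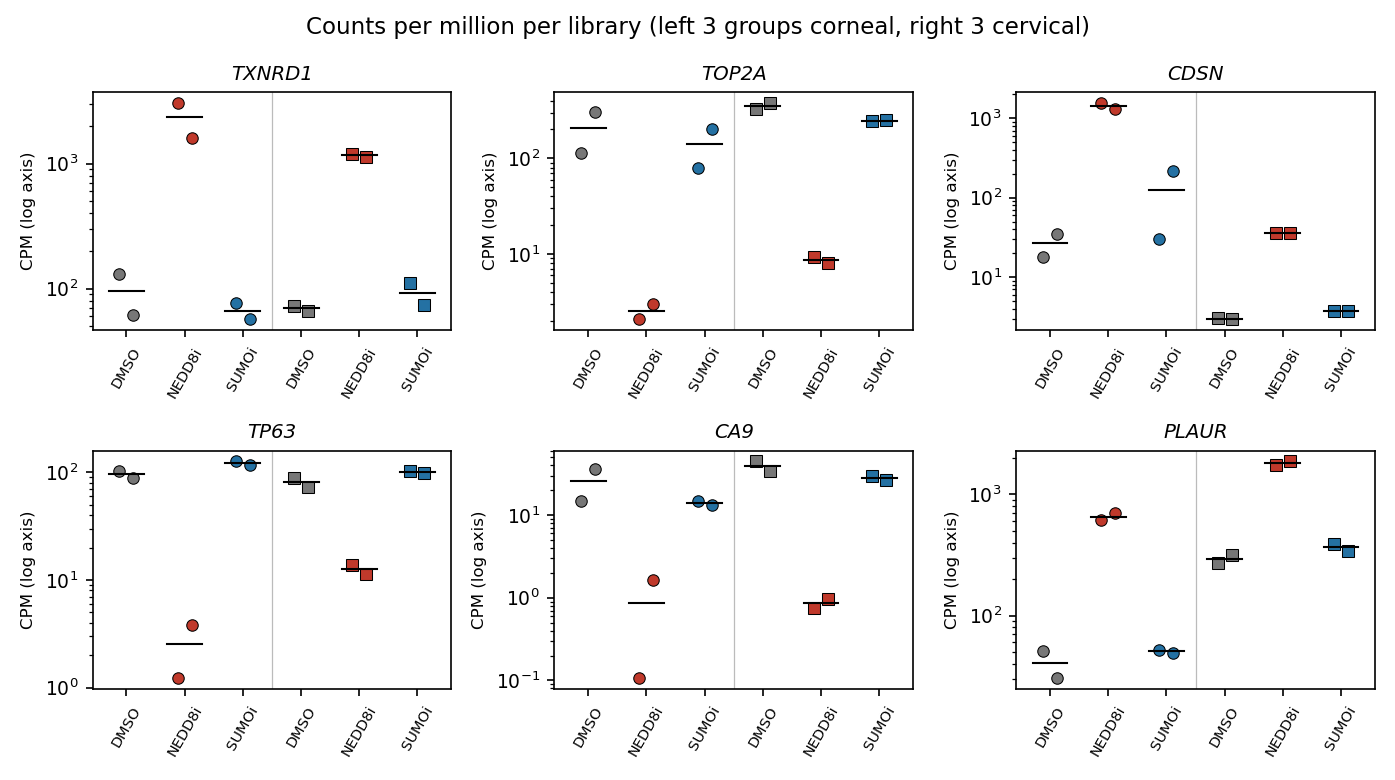
CPM on a log axis of 6 genes (TXNRD1, TOP2A, CDSN, TP63, CA9 and PLAUR) in DMSO, NEDD8i and SUMOi libraries of corneal (circles) and cervical cells (squares), with points for libraries and bars for the mean of 2. TXNRD1 averaged 2346 ± 1030 CPM in corneal and 1170 ± 48.9 CPM in cervical NEDD8i libraries, against 96.5 ± 48.7 and 69.7 ± 4.64 with DMSO (± SD).

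Immune and stress lists in corneal cells went both ways. Of 16 antigen presentation genes, 10 fell and 6 were not called, with 11 falling adjusted over the list alone (camera adjusted p = 0.00433, and adjusted p = 0.289 with an estimated correlation). The immunoproteasome subunit PSMB8 was 16.4-fold lower (36.8 without NEDD8i replicate 1) and the peptide-trimming ERAP1 14.5-fold lower (5.601 and 37.2 without NEDD8i replicates 1 and 2). Of 46 NF-kB and inflammatory genes, 17 rose, 4 fell and 25 were not called, the same counts adjusted over the list alone (camera adjusted p = 0.0412, and adjusted p = 0.922 with an estimated correlation). IL23A, a subunit of interleukin 23, rose 18.6-fold (56.4 and 11.5 without DMSO replicates 1 and 2, and 11.2 without NEDD8i replicate 1) and LCN2, the iron-scavenging lipocalin, 16.6-fold. That list's call was lost without corneal DMSO replicate 2 (camera adjusted p = 0.271) and without corneal NEDD8i replicate 2 (0.0745), and fry gave 0.0531. Over all alternatives its adjusted p ran from 0.00037 to 0.922. Of 28 immediate early genes, 15 rose, 4 fell and 9 were not called, with 16 and 4 adjusted over the list alone (camera adjusted p = 0.00546, and adjusted p = 0.526 with an estimated correlation). The nuclear receptor NR4A1 rose 82.4-fold and EGR3 53.9-fold, while MYC fell 13.1-fold and FOS 7.98-fold. Without DMSO replicates 1 and 2 the fold was 46.7 and 185 for NR4A1 and 30.5 and 174 for EGR3. Without NEDD8i replicate 1 it was 136 for NR4A1 and 4.61 for FOS, and without replicate 2 it was 30.5 for NR4A1, 27.0 for EGR3 and 12.8 for FOS. Of 19 endoplasmic reticulum chaperones, 12 fell, 2 rose and 5 were not called, as adjusted over the list alone (camera adjusted p = 0.0225, and adjusted p = 0.922 with an estimated correlation). CRELD2 of this list was lower (-2.46 on the log2 scale), and the call was lost without corneal DMSO replicate 2 (camera adjusted p = 0.122, and 7.22e-05 to 0.922 over all alternatives). All genes named here had an edgeR adjusted p of at most 0.00245.

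The other 20 lists were not called in corneal cells with NEDD8i, although single members were. Camera adjusted p was 0.78 for p53 targets, of which the kinase PLK3 rose 16.4-fold, GADD45A 5.06-fold and the secreted GDF15 4.16-fold, while the DNA repair genes XPC and DDB2 were lower (-2.81, or -3.75 without NEDD8i replicate 1, and -2.77 on the log2 scale). It was 0.805 for the NEDD8 pathway, where DCUN1D3, a NEDD8 ligase subunit, rose 8.35-fold and the cullin CUL3 3.38-fold. NEDD8 itself was measured at 0.40 ± 0.18 (log2) with an edgeR adjusted p of 0.0758. For NEDD8, the adjusted p was 0.0338 with DESeq2, 0.0442 with DESeq2 size factors, 0.0269 with replicate number as a block and 0.0395 without corneal DMSO replicate 1, and the sign turned with total-count scaling. Over all alternatives that p ran from 0.0269 to 0.461. For hypoxia targets the camera adjusted p was 0.269, and they were called lower without corneal DMSO replicate 1 (0.0339) or NEDD8i replicate 2 (0.0154, with 0.0154 to 0.922 over all alternatives). The mitophagy receptor BNIP3L rose 7.92-fold, and the carbonic anhydrase CA9 and NDRG1 fell 52.5-fold and 5.84-fold. The CA9 fold was 32.0 without DMSO replicate 2 and 16.1 and 229 without NEDD8i replicates 1 and 2, and the NDRG1 fold 10.03 without NEDD8i replicate 2. Interferon-stimulated genes (median log2 0.651) had 0.649, while antiviral TRIM22 fell 26.8-fold. Mesenchymal and wound-edge genes had 0.0945 and were called lower without corneal DMSO replicate 2 (0.00181) or NEDD8i replicate 2 (0.0132, with 0.00181 to 0.922 over all alternatives). PLAUR, the urokinase receptor, rose 16.1-fold and LOXL2, a collagen crosslinking enzyme, fell 63.5-fold (21.1 and 204 without NEDD8i replicates 1 and 2). The called genes of this paragraph had an edgeR adjusted p of at most 0.000198.

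Camera adjusted p in corneal cells was 0.0542 for cervical and Mullerian markers, 0.0844 for endothelial markers, 0.214 for cholesterol synthesis, 0.244 for proteasome subunits, and 0.269 for fibroblast markers and for ribosomal proteins. Cervical markers were called higher with fry (0.000556), in the fit of corneal libraries alone (0.0121), and without DMSO replicate 1 (0.00646), NEDD8i replicate 1 (0.037) or cervical SUMOi replicate 2 (0.0478). Endothelial markers were called higher with fry (0.000556), with a replicate block (0.0389), and without NEDD8i replicate 1 (0.037) or 2 (0.0237). Proteasome subunits were called higher without DMSO replicate 1 (0.0475). Cholesterol synthesis was called lower without DMSO replicate 2 (0.00386), ribosomal proteins without NEDD8i replicate 2 (0.034), and fibroblast markers (0.0272) and retrovirus-derived and germline genes (0.0223) with fry. Over all alternatives the highest adjusted p was 0.339 for cervical markers, 0.311 for endothelial markers and 0.922 for the other 5 lists. The mucin MUC16 rose 14.3-fold and the endothelial adhesion gene ESAM 134-fold (77.2 without DMSO replicate 2, 74.9 without NEDD8i replicate 1, and against 0 reads without DMSO replicate 1), while the collagen COL5A2 fell 30.5-fold (18.1 without NEDD8i replicate 1). For the remaining 9 lists (SUMO pathway, interferons and sensors, integrated stress response, heat shock, corneal markers, mitochondrially encoded transcripts, histones, senescence-associated secretory genes, and retrovirus-derived and germline genes) it was between 0.649 and 0.999. Fibroblast markers took 0.186% and 0.152% of reads with DMSO and 0.118% and 0.0906% with NEDD8i. The genes of this paragraph had an edgeR adjusted p of at most 1.71e-05. With total-count scaling in place of TMM, chosen after the data were seen, the median of all genes moved from -0.03 to -0.60 on the log2 scale, and 26.4% of the called genes rose against 49.3%. The changes given here are relative to the TMM scale. On the total-count scale the medians of the proteasome and histone lists, which were not called, turned from positive to negative.

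In cervical cells with NEDD8i 21 of 29 NRF2 targets rose, while 38 of 40 genes of G2/M and mitosis and 17 of 29 hypoxia targets fell. The adjusted p with an estimated correlation was 0.0239, 0.168 and 0.683 for these lists in turn. TXNRD1 rose 16.8-fold, from 69.7 ± 4.64 to 1170 ± 48.9 CPM (n = 2 and 2 libraries), and SLC7A11, the cystine transporter, rose 18.6-fold. The mitotic topoisomerase TOP2A (ENSG00000131747.15, chromosome 17, 40388525 to 40417896) was 40.6-fold lower and CA9 46.1-fold lower. HAS2, a hyaluronan synthase, rose 41.5-fold (5.38 ± 0.22 on the log2 scale) and SPP1, the secreted osteopontin, 70.0-fold. The cytokine LTB, with no read under NEDD8i, was at least 146-fold lower and the peptide hormone gene APLN 207-fold lower. ESM1 rose 149.9-fold and the aldehyde dehydrogenase ALDH3A1 46.3-fold. For these 10 genes the edgeR adjusted p lay between 6.76e-07 for HAS2 and 0.000259 for CA9. In all, 5028 genes (32.96%) were called, 2387 higher and 2641 lower. Leaving out 1 cervical DMSO or NEDD8i library gave fewer calls. A fit of the 6 cervical libraries alone gave 8498, including 4929 of the 5028 in the same direction. With total-count scaling the median of all genes moved from 0 to -0.171, and 33.9% of called genes rose against 47.5%.

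Of 29 NRF2 targets in cervical cells, 21 rose and 8 were not called, with 22 rising adjusted over the list alone (camera adjusted p = 1.69e-20, and adjusted p = 0.0239 with an estimated correlation). AKR1C1 rose 39.7-fold. Of 38 genes of G1/S and replication, 27 fell and 11 were not called, with 29 falling adjusted over the list alone (camera adjusted p = 2.59e-16, and adjusted p = 0.032 with an estimated correlation). RRM2 fell 10.4-fold and the replication licensing factor CDT1 7.69-fold. Of 40 genes of G2/M and mitosis, 38 fell and 2 were not called, with 38 adjusted over the list alone (camera adjusted p = 4.66e-39, and adjusted p = 0.168 with an estimated correlation). Of 29 hypoxia targets, 17 fell, 1 rose and 11 were not called, with 19 and 1 adjusted over the list alone (camera adjusted p = 1.88e-05, and adjusted p = 0.683 with an estimated correlation). The glycolytic regulator PFKFB4 was 9.93-fold lower. Without cervical DMSO replicate 1 or 2, 10 hypoxia genes fell, and without cervical NEDD8i replicate 1 or 2, 9 fell. Of 29 proteasome subunits, 16 rose and 13 were not called, with 20 rising and 1 falling adjusted over the list alone (camera adjusted p = 0.00114, and adjusted p = 0.683 with an estimated correlation). That count was 5 without cervical DMSO replicate 1 or 2, 3 without cervical NEDD8i replicate 1 and 4 without replicate 2. Of 16 antigen presentation genes, 6 fell and 10 were not called, as they did adjusted over the list alone (camera adjusted p = 0.00394, and adjusted p = 0.288 with an estimated correlation). PSMB8 fell 3.67-fold. That list's count was 3 without cervical DMSO replicate 2 or NEDD8i replicate 2, and 15 in the fit of cervical libraries alone. The edgeR adjusted p of the genes named here was at most 0.00231.

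Differentiation, junction and basal lists were called in cervical cells as well. Of 50 genes of squamous differentiation, 19 rose, 1 fell and 30 were not called, with 19 and 1 adjusted over the list alone (camera adjusted p = 2.42e-05, and adjusted p = 0.683 with an estimated correlation). PRDM1, a transcription factor of terminal differentiation, rose 8.70-fold, and S100A7, a calcium-binding protein with close paralogs, was the member that fell, 12.4-fold. CDSN rose 12.1-fold (edgeR adjusted p = 0.0106), a call lost without cervical DMSO replicate 1 (0.064), without replicate 2 (0.0675) and without the count filter (0.0546), with 1.85e-10 to 0.0675 over all alternatives. The count of rising genes was 8 and 9 without cervical DMSO replicates 1 and 2, 11 without either NEDD8i replicate, and 37 in the fit of cervical libraries alone. With fry the list had an adjusted p of 0.0502. Of 31 junction genes, 15 rose, 3 fell and 13 were not called, with 16 and 3 adjusted over the list alone (camera adjusted p = 0.000234, and adjusted p = 0.288 with an estimated correlation). The claudin CLDN4 rose 6.72-fold and TJP3 4.98-fold. Without cervical DMSO replicate 1 or 2, 9 junction genes rose, and the fit of cervical libraries alone gave 23. Of 24 basal epithelial genes, 11 fell, 2 rose and 11 were not called, the same counts adjusted over the list alone (camera adjusted p = 0.000241, and adjusted p = 0.294 with an estimated correlation). The integrin ITGB4 fell 8.40-fold, while the keratin KRT14, which has close paralogs, rose 6.49-fold. Of 28 immediate early genes, 12 rose, 4 fell and 12 were not called, with 13 and 4 adjusted over the list alone (camera adjusted p = 0.00137, and adjusted p = 0.425 with an estimated correlation). The stress transcription factor ATF3 rose 7.66-fold, NR4A1 rose 39.3-fold and MYC fell 3.70-fold. Apart from CDSN, the edgeR adjusted p of the genes named here was at most 0.00326.

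Of 19 corneal epithelium markers, 6 rose and 13 were not called in cervical cells, with 7 adjusted over the list alone (camera adjusted p = 0.0112, and adjusted p = 0.683 with an estimated correlation). The water channel AQP5 of that list rose 7.31-fold, and fry gave the list an adjusted p of 0.0649. The other 19 lists were not called in cervical cells. Camera adjusted p was 0.123 for cholesterol synthesis, and 0.222 for the integrated stress response, mitochondrially encoded transcripts and ribosomal proteins. It was 0.27 for mesenchymal and wound-edge genes, where PLAUR rose 6.15-fold. It was 0.626 for the NEDD8 pathway, with DCUN1D3 5.05-fold higher, and 0.643 for p53 targets, with GDF15 4.91-fold higher and the death receptor FAS 2.85-fold lower. For cervical and Mullerian markers it was 0.603. The other lists lay between 0.288 and 0.96. With fry the SUMO pathway (0.0132) and the integrated stress response (0.0472) were called higher and interferons and sensors lower (0.0214), each with up to 0.683 over all alternatives. In the fit of cervical libraries alone mesenchymal (0.0114) and cholesterol genes (0.0443) were called lower, with up to 0.831 over all alternatives. Fibroblast markers took 0.0126% and 0.0121% of reads with DMSO and 0.0279% and 0.0265% with NEDD8i, and their camera adjusted p was 0.643. The edgeR adjusted p of the genes of this paragraph was at most 0.00252.

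**Figure D3:**
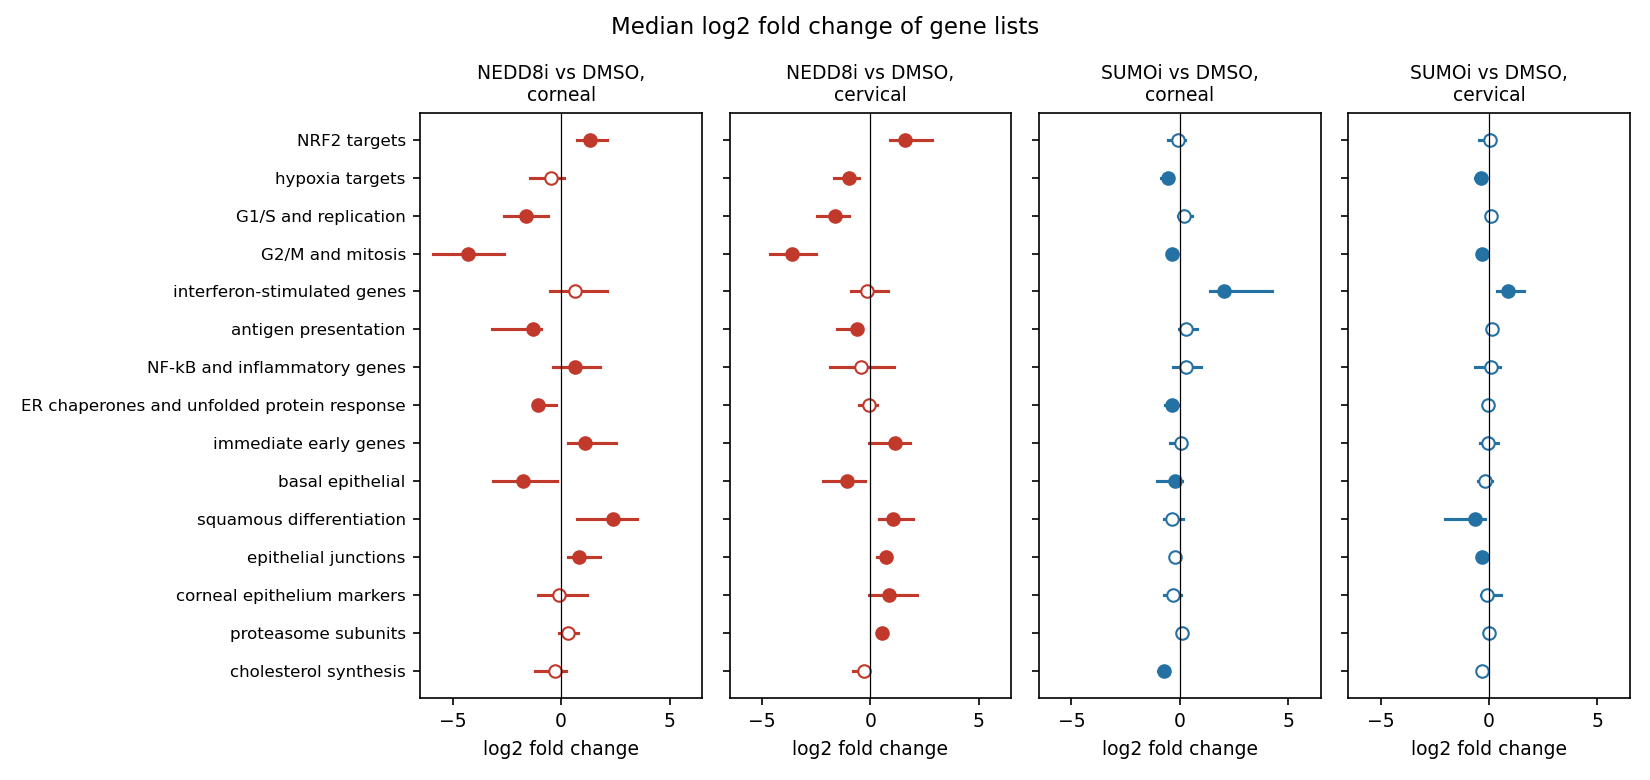
Median log2 fold change of 15 gene lists in the inhibitor comparisons (points, with lines over the middle quartiles of the members; filled points are lists called by camera). The NRF2 median lies above 0 and the G2/M median below 0 in both NEDD8i comparisons; with members at 0 reads put at their bound, the cervical basal median is -0.618 in place of -1.10.

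SUMOi changed fewer genes. In corneal cells the largest rises included OLAH, a thioesterase of fatty acid synthesis (ENSG00000152463.15, chromosome 10, 15043943 to 15073853), which rose 71.0-fold (6.15 ± 0.61 on the log2 scale). TXNIP, an inhibitor of thioredoxin, rose 58.0-fold (88.2 and 26.9 without SUMOi replicates 1 and 2), the decoy chemokine receptor ACKR2 31.4-fold (17.98 and 77.2 without DMSO replicates 1 and 2) and DHRS2, a dehydrogenase, 29.7-fold. The growth factor gene PDGFB fell 5.81-fold, the metalloproteinase inhibitor TIMP2 5.10-fold, the uridine phosphorylase UPP1 4.80-fold and TMEM200A 10.1-fold (16.6 without SUMOi replicate 1). AQP3, a water and glycerol channel, rose from 778 ± 430.4 to 7557 ± 659 CPM (n = 2 and 2 libraries). For these 9 genes the edgeR adjusted p lay between 3.08e-05 for DHRS2 and 0.0127 for AQP3. In all, 616 genes were called, 302 higher and 314 lower. A fit of the 6 corneal libraries alone called 10 genes, all among the 616, and of the genes named here DHRS2 was among them while the edgeR adjusted p of the other 8 ran from 0.0581 to 0.121. DESeq2 called 1157 genes, the fit with replicate number as a block 944, the fit without a count filter 1420, and leaving out corneal SUMOi replicate 1 gave 308. With total-count scaling 59.9% of the called genes rose against 49%.

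Of 41 interferon-stimulated genes in corneal cells with SUMOi, 5 rose and 36 were not called, with 32 rising adjusted over the list alone (camera adjusted p = 9.37e-15, and adjusted p = 0.649 with an estimated correlation and 0.174 with fry). IFI44 (ENSG00000137965.11, chromosome 1, 78649831 to 78664073) averaged 17.1 ± 19.3 CPM with SUMOi and 0.197 ± 0.0998 with DMSO (edgeR adjusted p = 0.0233). The ISG15 ligase HERC5 averaged 45.9 ± 53.8 against 0.776 ± 0.291 CPM (adjusted p = 0.0299) and the chemokine CXCL10 14.2 ± 14.4 against 0.998 ± 0.0227 (adjusted p = 0.0246). Their log2 fold changes were 6.46, 5.92 and 3.81, 7.30, 6.78 and 4.59 without SUMOi replicate 1 and 4.12, 3.33 and 1.94 without replicate 2. The SUMOi replicates differed: the median member lay 0.60 above the DMSO mean in replicate 1 and 2.81 above it in replicate 2, on the log2 scale. The count of rising members was 32 without SUMOi replicate 1, 6 without SUMOi replicate 2, 1 without DMSO replicate 1, 0 without DMSO replicate 2 and 0 in the fit of corneal libraries alone, where DESeq2 on all libraries gave 28. The IFI44 call was lost without DMSO replicate 1 (0.108), without DMSO replicate 2 (0.0985), without a filter (0.0739) and in the corneal fit (0.212). For HERC5 these adjusted p were 0.134, 0.131, 0.0889 and 0.245. CXCL10 had 0.0954 and 0.105 without DMSO replicates 1 and 2, 0.0831 without SUMOi replicate 2, 0.053 at equal depth and 0.25 in the corneal fit. Over all alternatives the adjusted p ran from 1.53e-09 to 0.212 for IFI44, from 1.04e-05 to 0.245 for HERC5 and from 1.95e-13 to 0.25 for CXCL10.

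A further 5 lists were called in corneal cells with SUMOi, all of them lower. Of 22 cholesterol synthesis genes, 4 fell and 18 were not called, with 15 falling adjusted over the list alone (camera adjusted p = 6.77e-08, and adjusted p = 0.649 with an estimated correlation). IDI1, an isomerase of that pathway, fell 2.62-fold, and the count was 1 without DMSO replicate 1 or SUMOi replicate 1 and 15 without DMSO replicate 2. Of 29 hypoxia targets, 2 fell and 27 were not called, with 4 falling adjusted over the list alone (camera adjusted p = 4.61e-06, and adjusted p = 0.649 with an estimated correlation). They were ADM, the vasodilator adrenomedullin, which fell 4.38-fold, and the endoplasmic reticulum oxidase ERO1A, which fell 2.96-fold. That count was 5 without DMSO replicate 1. Of 24 basal epithelial genes, 4 fell, with 6 falling and 1 rising adjusted over the list alone (camera adjusted p = 0.0293, and adjusted p = 0.649 with an estimated correlation). The basal call was lost without DMSO replicate 1 (camera adjusted p = 0.23) and without SUMOi replicate 1 (0.149), and the count was 2 without DMSO replicate 1 or SUMOi replicate 2 and 0 without SUMOi replicate 1. Of 19 endoplasmic reticulum chaperones, 2 fell, with 5 falling and 1 rising adjusted over the list alone (camera adjusted p = 0.0104, and adjusted p = 0.686 with an estimated correlation). Without DMSO replicate 2 this call was lost (camera adjusted p = 0.763), and the count was 5 without DMSO replicate 1 and 0 without each of the other 3 libraries. The G2/M list was lower by camera alone (adjusted p = 0.0104, and adjusted p = 0.806 with an estimated correlation). By edgeR 0 of its 40 members were called, and camera lost it without SUMOi replicate 1 or DMSO replicate 2, where the direction turned. TOP2A, its member with the highest level, was measured at -0.58 ± 0.48 (log2, edgeR adjusted p = 0.557). The sign turned without DMSO replicate 2, but within replicate numbers TOP2A fell (113 to 79.4 and 306 to 201 CPM). In the fit of the corneal libraries alone 0 members of these lists were called by edgeR, and fry called none of them.

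The other 24 lists were not called in corneal cells with SUMOi. Camera adjusted p was 0.056 for ribosomal proteins, 0.0692 for G1/S, NF-kB, squamous and junction genes, and 0.159 for p53 targets, antigen presentation and senescence-associated secretory genes. MDM2, the ubiquitin ligase of p53, rose 2.83-fold and GDF15 6.72-fold, while PTGS2, a prostaglandin synthase, fell 2.27-fold. S100A7 rose 5.43-fold and CCN2, a matricellular growth factor, 3.05-fold. Camera adjusted p was 0.345 for the SUMO pathway, where the desumoylating protease DESI2 rose 2.88-fold. SUMO2 was measured at 0.35 ± 0.19 (log2, edgeR adjusted p = 0.352). The other lists lay between 0.17 and 0.912. Of these 24 lists, 12 were called under alternatives. Without DMSO replicate 1 the camera adjusted p was 9.58e-06 for NF-kB genes, 0.0141 for proteasome subunits and 0.0473 for mitochondrially encoded and senescence genes, all higher, and 9.05e-05 for squamous genes, 0.0221 for junction genes and 0.00485 for corneal markers, all lower. Without DMSO replicate 2 ribosomal proteins were higher (0.00269) and mesenchymal genes lower (0.00201). Without SUMOi replicate 1 G1/S (0.00736), antigen presentation (0.00736) and retrovirus-derived and germline genes (0.0108) were higher. Without SUMOi replicate 2 NF-kB genes (1.03e-05) and proteasome subunits (0.0372) were higher and squamous genes (5.1e-10), junction genes (0.00497) and corneal markers (0.00473) lower. A replicate block gave 0.037 for NF-kB genes, higher, 0.037 for junction genes, lower, and 0.0263 for ribosomal proteins, higher. Leaving out corneal NEDD8i replicate 1 gave 0.0473 for ribosomal proteins, and leaving out replicate 2 gave 0.0111 for them and 0.0319 for junction genes. Over all alternatives the highest adjusted p of these 12 lists lay between 0.649, for junction genes, and 0.963, for mesenchymal genes. The called genes of this paragraph and IDI1, ADM and ERO1A had an edgeR adjusted p of at most 0.00944 and were not called in the fit of corneal libraries alone, where it ran from 0.0595 for GDF15 to 0.155 for PTGS2.

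In cervical cells SUMOi raised OLAH 197-fold (7.62 ± 0.61 on the log2 scale) and SLITRK6, a neuronal membrane protein, 7.84-fold. SPRR2E, a cornified envelope protein with close paralogs, fell 8.47-fold, from 144 ± 16.8 to 17.0 ± 1.47 CPM (n = 2 and 2 libraries). The serpin SERPINB7 fell 9.85-fold and the annexin ANXA9 9.92-fold. The edgeR adjusted p was 0.00034 for OLAH, 0.00188 for SLITRK6, 0.00138 for SPRR2E, 0.000705 for SERPINB7 and 0.00121 for ANXA9. In all, 606 genes were called, 295 higher and 311 lower. Leaving out 1 cervical DMSO or SUMOi library gave far fewer calls. The fit of the 6 cervical libraries alone called 3638 genes, among them 602 of the 606 in the same direction. DESeq2 called 951 genes, the fit without a count filter 1243, and the fit at equal depth 387. With total-count scaling 60.7% of called genes rose against 48.7%.

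Of 50 genes of squamous differentiation in cervical cells with SUMOi, 8 fell and 42 were not called, with 14 falling and 1 rising adjusted over the list alone (camera adjusted p = 7.14e-11, and adjusted p = 0.966 with an estimated correlation). Involucrin, IVL, fell 9.94-fold (log2 -3.31, edgeR adjusted p = 0.00646). The call was lost without DMSO replicate 2 or either SUMOi replicate, where the log2 value was -3.34 to -3.27. The list's count was 4 and 3 without DMSO replicates 1 and 2, 2 without either SUMOi replicate and 31 in the cervical fit alone. Of 31 junction genes, 2 fell, with 3 adjusted over the list alone (camera adjusted p = 0.00839, and adjusted p = 0.966 with an estimated correlation). Without any 1 of the 4 libraries 0 were called, and in the cervical fit alone 12 fell and 2 rose. Of 29 hypoxia targets, 2 fell, with 2 adjusted over the list alone (camera adjusted p = 0.00417, and adjusted p = 0.998 with an estimated correlation). ADM fell 2.79-fold (log2 -1.48, edgeR adjusted p = 0.00295), a call lost without SUMOi replicate 1 (log2 -1.5) or 2 (-1.46). The hypoxia count was 1 without either DMSO replicate, 0 without either SUMOi replicate and 17 in the cervical fit alone. Of 41 interferon-stimulated genes 1 rose, the same adjusted over the list alone (camera adjusted p = 0.000789, and adjusted p = 0.998 with an estimated correlation). That count was 0 without each of the 4 libraries, while the cervical fit alone gave 29 rising and 2 falling. The G2/M list was lower by camera (adjusted p = 0.025, and adjusted p = 0.998 with an estimated correlation), which was lost without DMSO replicate 2 (0.0694). By edgeR 0 of its 40 members were called in the 12-library fit and 13 fell in the cervical fit alone, and TOP2A was measured at -0.51 ± 0.48 (log2, edgeR adjusted p = 0.691, and 0.00202 in the cervical fit, with 0.00202 to 0.991 over all alternatives). None of these lists was called by fry.

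MDM2 rose 2.46-fold in cervical cells with SUMOi (log2 1.3, edgeR adjusted p = 0.0036). The call was lost without DMSO replicate 1 (log2 1.17) or SUMOi replicate 2 (1.27). The cadherin CDH2 fell 7.51-fold (log2 -2.91, adjusted p = 0.00208), lost without SUMOi replicate 1 (-2.75). The cervical fit alone kept the calls of IVL, ADM, MDM2 and CDH2. SUMO2 was measured at 0.55 ± 0.19 (log2, edgeR adjusted p = 0.159, and 0.00135 in the cervical fit alone, with 0.00135 to 0.642 over all alternatives). The other 25 lists had a camera adjusted p between 0.185 and 0.997. Cholesterol synthesis among them was called lower in the cervical fit alone (0.0398) and without corneal DMSO replicate 1 (0.0479), with up to 0.998 over all alternatives.

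**Figure D4:**
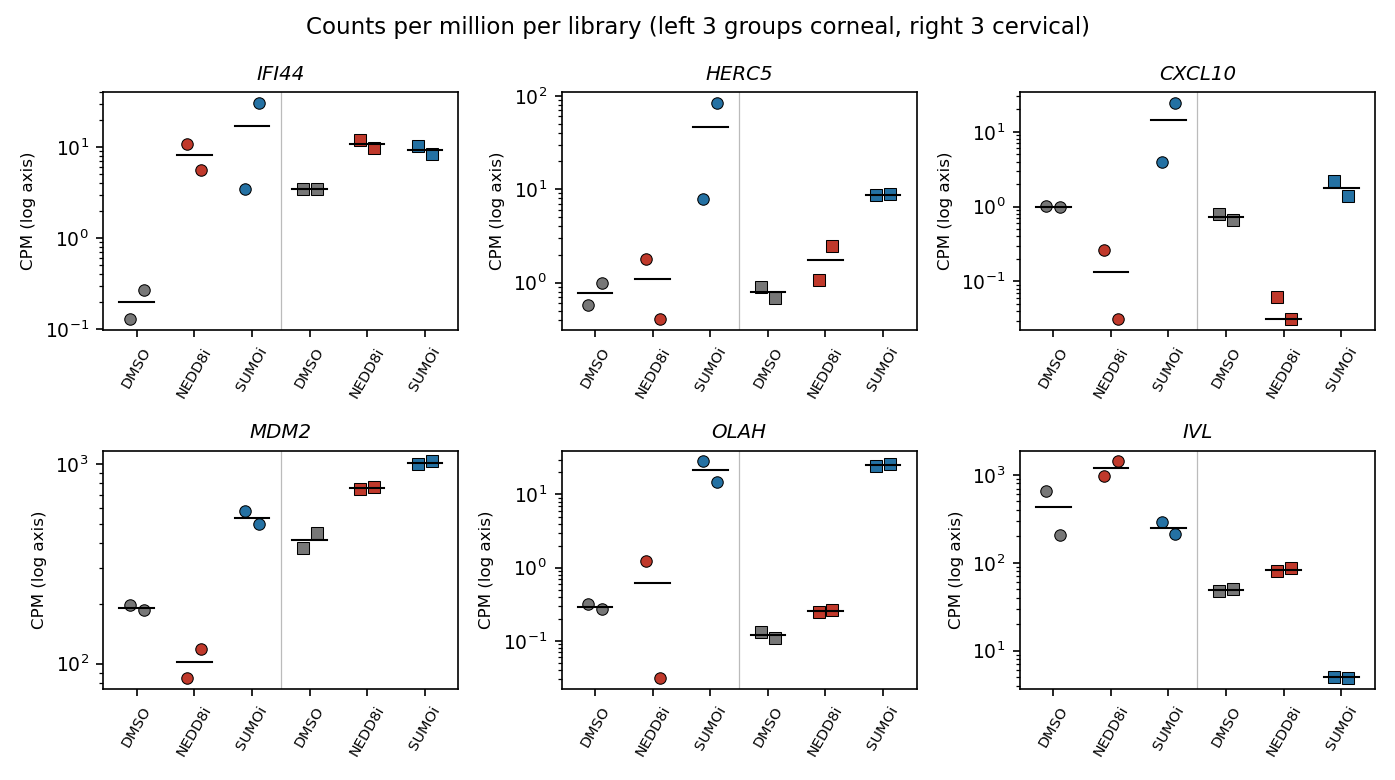
CPM on a log axis of 6 genes (IFI44, HERC5, CXCL10, MDM2, OLAH and IVL) in DMSO, NEDD8i and SUMOi libraries of corneal (circles) and cervical cells (squares), with points for libraries, bars for the mean of 2, and libraries at 0 drawn at 1 read of the deepest library. IFI44 averaged 17.1 ± 19.3 CPM (± SD) in corneal SUMOi libraries, so its points lie far apart.

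In the direct comparison of the inhibitors in the same cells DMSO libraries enter the shared spread but not the fold changes. The inhibitors may also differ in treatment time, since that of SUMOi is not given. In corneal cells AQP5 was at least 670.5-fold higher with NEDD8i than with SUMOi and the septin SEPTIN3 at least 434-fold higher, each without a read under SUMOi. MXRA5 was at least 262-fold lower (at least 155 without SUMOi replicate 2) and the cell cycle phosphatase CDC25B 183-fold lower (481 without NEDD8i replicate 1). In cervical cells ESM1 was at least 228-fold higher with NEDD8i, LTB at least 119-fold lower, and APLN and SLITRK6 172-fold and 103-fold lower (243 for SLITRK6 without NEDD8i replicate 1). In these 8 genes the edgeR adjusted p was at most 0.000334, for MXRA5. In corneal cells 8686 genes differed, 4163 higher and 4523 lower with NEDD8i, and in cervical cells 6437 differed, 3204 higher and 3233 lower. The cervical count was 4083 and 4040 without NEDD8i replicates 1 and 2, and 3875 and 3911 without SUMOi replicates 1 and 2. With total-count scaling the medians of all genes were -0.757 in corneal and -0.27 in cervical cells, and the called genes were 2490 higher and 7421 lower in corneal and 2141 higher and 4443 lower in cervical cells.

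Whether the response to NEDD8i differed between the cell types was tested as an interaction. ANKRD1, a muscle ankyrin repeat protein, differed by 9.90 ± 0.85 on the log2 scale, with a corneal log2 fold change of 8.475 and a cervical one of -1.43 (edgeR adjusted p = 0.0756). The difference was 8.70 without corneal DMSO replicate 1 and 14.72, against 0 reads, without replicate 2. TP63 fell further in corneal cells (-2.85 ± 0.46, with -1.96 and -3.57 without corneal NEDD8i replicates 1 and 2), as did TYMS (-3.66 ± 0.35). S100A7 (6.12 ± 0.57) and LCN2 (3.97 ± 0.35) were higher in the corneal response, and ALDH3A1 (-5.62 ± 0.75, and -4.93 without corneal DMSO replicate 2) and KRT14 (-3.43 ± 0.36) lower. MITF, the transcription factor of melanocytes and other cells, was higher with NEDD8i in corneal cells (2.88 on the log2 scale) and lower in cervical cells (-2.07), a difference of 4.95 ± 0.32. For these 8 differences the edgeR adjusted p was at most 0.0028, for TP63. In all, 2297 genes differed, 1240 with a higher and 1057 with a lower corneal response. Without cervical DMSO replicates 1 and 2 the count was 1101 and 1114, without cervical NEDD8i replicates 1 and 2 it was 1008 and 1040, and total-count scaling gave 3469, 831 higher and 2638 lower, with the median of all genes at -0.406.

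Camera called 7 lists for this difference and none with an estimated correlation (adjusted p 0.751 to 0.807) or with fry (0.0737 to 0.253). NF-kB genes (10 members higher, 2 lower of 46, the same adjusted over the list alone, camera adjusted p = 0.000436) and squamous genes (9 higher of 50, 9 adjusted over the list alone, 0.000436) stood higher in the corneal response. Fibroblast markers stood lower (2 of 15, 2 adjusted over the list alone, 0.0202). The calls of the other 4 lists were each lost without single libraries. Hypoxia targets, higher at 0.0224, reached 0.114 without corneal DMSO replicate 1 and 0.498 without corneal NEDD8i replicate 2. Chaperones, lower at 0.0202, reached 0.158 without corneal DMSO replicate 2. Basal genes, lower at 0.0288, reached 0.107 without corneal DMSO replicate 1, 0.0726 without corneal NEDD8i replicate 1, 0.0606 without cervical DMSO replicate 1 and 0.0543 with a replicate block. Ribosomal proteins, lower at 0.00701, reached 0.0643 without corneal DMSO replicate 2 and 0.0583 without corneal NEDD8i replicate 1. Other lists were called without single libraries. Without corneal DMSO replicate 1 the G2/M list (0.00114), NRF2 targets (0.0342) and corneal markers (0.0128) were lower and cervical markers higher (0.0104). Mitochondrially encoded transcripts were lower without corneal DMSO replicate 2 (0.00591), without corneal NEDD8i replicate 1 (0.00244) and with a replicate block (0.038), and NRF2 targets without corneal NEDD8i replicate 1 (0.00958). For these 5 lists the highest adjusted p over all alternatives was 0.751 to 0.807.

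For SUMOi, the interaction test called 18 genes, 14 with a higher and 4 with a lower corneal response, and 1063 at an unadjusted p below 0.05. The collagen COL18A1 (3.42 ± 0.35, edgeR adjusted p = 0.00575) and ACKR2 (4.01 ± 0.53, 0.0142) were higher and UPP1 was lower (-2.46 ± 0.33, 0.0142). Some calls were lost without 1 library, with 3.38 to 3.45 for COL18A1, 3.92 to 4.08 for ACKR2 and -2.55 to -2.25 for UPP1 where they were lost. Without cervical SUMOi replicates 1 and 2 the adjusted p was 0.0887 and 0.0847 for COL18A1, 0.161 and 0.108 for ACKR2, and 0.0887 and 0.104 for UPP1. Without cervical DMSO replicates 1 and 2 it was 0.0925 and 0.104 for ACKR2 and 0.115 and 0.117 for UPP1, and without corneal SUMOi replicate 2 0.0515 for UPP1. Without corneal DMSO replicates 1 and 2 ACKR2 kept its call, at 3.21 and 5.33. Over all alternatives p was 9.56e-19 to 0.0887, 3.47e-15 to 0.161 and 1.02e-11 to 0.117 for the same 3 genes. DESeq2 called 136, the fit without a filter 254, the replicate block 37 and equal depth 11. Without single libraries the count was 44, 33 and 94 for corneal DMSO replicates 1 and 2 and SUMOi replicate 1, and 2, 4, 0 and 0 for cervical DMSO replicates 1 and 2 and SUMOi replicates 1 and 2 (the zeros with 633 and 658 genes at an unadjusted p below 0.05). Camera called 5 lists, all lost with an estimated correlation (adjusted p = 0.993) and with fry (0.748). Interferon-stimulated genes were called higher (9.8e-08, and 0.472 without corneal SUMOi replicate 2, where the direction turned) and squamous genes higher (2.74e-07, and 0.467 without the same library). Chaperones were lower (0.00344, and 0.686 without corneal DMSO replicate 2) and so was cholesterol synthesis (0.000148, and 0.684 without corneal DMSO replicate 1). Ribosomal proteins were called higher (0.0312), with 0.677 without corneal DMSO replicate 1, 0.112 without corneal SUMOi replicate 2, 0.109 without cervical DMSO replicate 1 and 0.165 without cervical SUMOi replicate 1. Other lists were called without single libraries. The G2/M list was lower without corneal DMSO replicate 1 (0.000341) and SUMOi replicate 2 (0.00151) and higher without DMSO replicate 2 (0.00216). NF-kB genes were higher without corneal DMSO replicate 1 (3.58e-07), corneal SUMOi replicate 2 (6.77e-06), cervical DMSO replicate 2 (0.0231) or cervical SUMOi replicate 2 (0.0386) and with a replicate block (0.034). Without corneal DMSO replicate 1 hypoxia targets were lower (0.00131) and proteasome subunits higher (0.0258), the latter also without corneal SUMOi replicate 2 (0.0307). Without corneal DMSO replicate 2 basal (0.000237) and mesenchymal genes (0.00677) were lower and histones higher (0.0107), and without corneal SUMOi replicate 1 G1/S genes (0.0225) and histones (0.0221) were higher. The highest adjusted p of these 8 lists was 0.993 to 0.999 over all alternatives.

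With DMSO alone, the genes with the largest differences between corneal and cervical cells included keratin, cadherin and transcription factor genes. The corneal keratin KRT12 was at least 2400-fold higher in corneal cells and the transcription factor DMRTA2 at least 3737-fold higher, at 109 ± 126 and 169 ± 146 CPM. These bounds were 430 and 1457 without corneal DMSO replicate 2 and 4369 and 6018 without replicate 1. The desmosomal cadherin DSG1 averaged 3483 ± 2821 against 0.202 ± 0.143 CPM. The eye transcription factor PAX6, with 1 read in cervical libraries, averaged 255 ± 146 against 0.0167 ± 0.0236 CPM. Transcription factors without a read in corneal libraries included HOXB6 (at least 243-fold lower), LHX1 (at least 210.4) and SOX17 (at least 204). The largest edgeR adjusted p was 0.0141, for KRT12, whose call was lost without cervical DMSO replicate 2 (0.0555), without a filter (0.076) and at equal depth (0.0588), with 8.12e-09 to 0.076 over all alternatives. In all, 4458 genes differed, 2169 higher and 2289 lower in corneal cells, with 2664 and 2154 without cervical DMSO replicates 1 and 2. Cell type, donor and culture conditions cannot be separated in this comparison, and all 12 samples carry the tissue label cornea.

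Overlaps between comparisons were counted by gene and direction. For NEDD8i, 3505 genes were called in the same direction in both cell types (1669 higher and 1836 lower, against 608.2 and 691.1 by chance) and 178 in opposite directions. Across genes, which are not independent replicates, the fold changes had Pearson r 0.618 and Spearman rho 0.632. The shared count was 2185 and 2187 without cervical DMSO replicates 1 and 2 and 2122 and 2063 without cervical NEDD8i replicates 1 and 2. For SUMOi, 205 genes were shared (106 higher and 99 lower, against 5.84 and 6.4 by chance), 5 went in opposite directions, and r was 0.459 and rho 0.44 across genes. That count was 133 without corneal SUMOi replicate 1, 26 without either cervical DMSO replicate, 25 and 23 without cervical SUMOi replicates 1 and 2, 381 with DESeq2, 483 without a filter, 318 with a replicate block and 128 at equal depth.

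NEDD8i and SUMOi shared 158 calls in corneal cells (75 higher and 83 lower, against 76.95 and 82.17 by chance), while 239 genes were called in opposite directions against 159 by chance. In cervical cells they shared 116 (56 and 60, against 46.16 and 53.84), with 198 opposite against 99.73. Both inhibitors share DMSO libraries, so part of any excess of shared calls may come from these controls. Simulated groups without change shared 0.15 and 0.05 calls on average, but this cannot size that part, as few genes are called where none change. Their covariance of fold changes across genes was 0.127 and 0.0856, against 0.0927 and -0.0883 in the data. The corneal count was 239, 276 and 91 without NEDD8i replicates 1 and 2 and SUMOi replicate 1, 2 in the fit of corneal libraries alone, 286 with DESeq2, 375 without a filter and 246 with the block. The cervical count was 14, 15, 44, 41, 16 and 11 without replicates 1 and 2 of DMSO, NEDD8i and SUMOi in that order, 957 in the cervical fit alone, 226 without a filter, 180 with the block and 63 at equal depth.

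**Figure D5:**
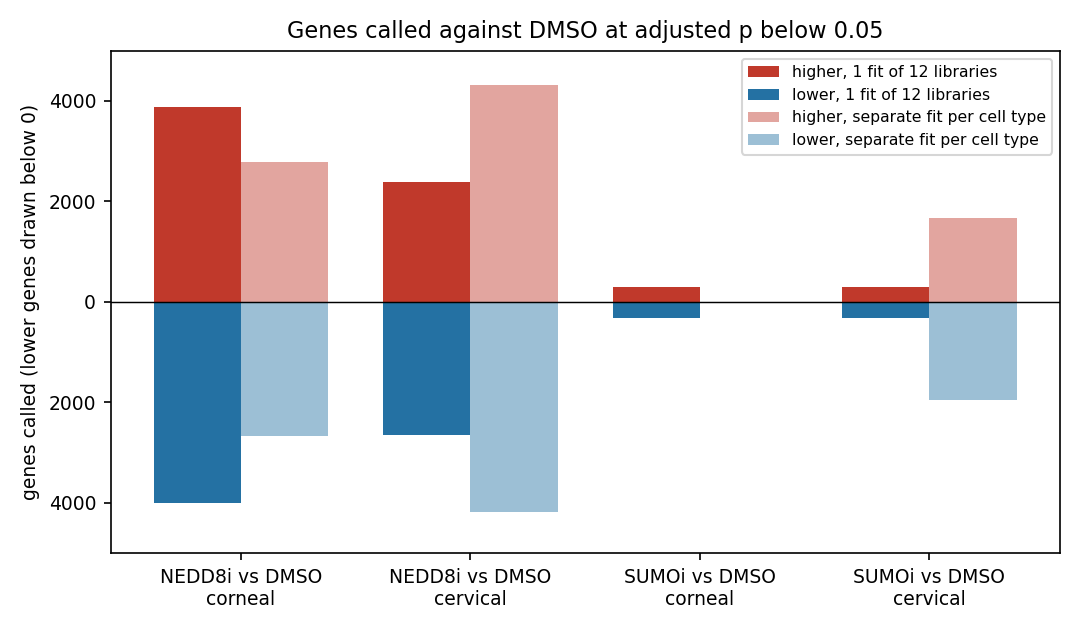
Genes called higher (bars above 0) and lower (bars below 0) per inhibitor and cell type, in the fit of all 12 libraries and in separate fits of each cell type. SUMOi gives 616 and 606 calls in corneal and cervical cells in the fit of 12 libraries, and 10 and 3638 in the separate fits.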

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

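Apart from the test for a response in corneal SUMOi replicate 1, the tests below were chosen after the results they measure were seen. Flagged first are inhibitor effects that differed between corneal and cervical cells in the edgeR interaction test. It called 2297 genes for NEDD8i and 18 for SUMOi. Values are corneal minus cervical log2 fold changes.

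Higher in the corneal response to NEDD8i were TLR10 (9.82), ANKRD1 (9.90), S100A7 (6.12), TRIM63 (6.05), MITF (4.95), IL23A (4.95), ESAM (4.91), AQP5 (4.68), LCN2 (3.97), HAS2 (3.35), KLK6 (3.29), HMOX1 (2.68), BNIP3L (2.41), E2F2 (2.40), PLK3 (2.25), E2F7 (1.995), MUC16 (1.93), PFKFB4 (1.69) and PLAUR (1.39). Lower were MXRA5 (-9.92), ALDH3A1 (-5.62), TRIM22 (-3.85), TYMS (-3.66), KRT14 (-3.43), UBE2C (-2.87), TP63 (-2.85), SLC7A11 (-2.49), COL5A2 (-2.48), PSMB8 (-2.16), DDB2 (-1.77) and CBR1 (-1.29). For SUMOi, CDH2 (4.63), ACKR2 (4.01) and COL18A1 (3.42) were higher and UPP1 (-2.46) lower in the corneal response.

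TLR10 and MXRA5 had no read in 1 of the groups compared, HAS2 had 1 and TRIM63 had 2. Their fitted values depend on the prior count and are no bounds. Single libraries moved some values. Without corneal DMSO replicate 1 ANKRD1 was at 8.70, IL23A at 6.55, ESAM at 9.33, AQP5 at 3.63, HAS2 at 5.96 and MXRA5 at -10.61. Without replicate 2 these were 14.72, 4.31, 4.16, 7.16, 2.69 and -8.64, and ALDH3A1 -4.93. Without corneal NEDD8i replicate 1 IL23A was at 4.24, ESAM at 4.08, UBE2C at -7.40, PSMB8 at -3.31, COL5A2 at -1.70 and TP63 at -1.96, without replicate 2 TP63 at -3.57, and without cervical DMSO replicate 1 TLR10 at 8.89. ESAM and HAS2 without DMSO replicate 1, ANKRD1 without DMSO replicate 2 and UBE2C had 0 reads in a group. For SUMOi, ACKR2 was at 3.21 and 5.33 without corneal DMSO replicates 1 and 2. Several of the 31 NEDD8i calls ended without single libraries. For HMOX1 the edgeR adjusted p was 0.0634 to 0.108 without any 1 of the 8 libraries, that of PSMB8 0.0567 to 0.151 without each library but cervical DMSO replicate 1, and that of UBE2C 0.0606 to 0.0935 without each library but the corneal DMSO ones. For MXRA5 it was 0.135 without corneal NEDD8i replicate 1, 0.0537 and 0.0549 without cervical DMSO replicates 1 and 2, and 0.0647 without cervical NEDD8i replicate 1. For PFKFB4 it was 0.123 without corneal NEDD8i replicate 1, 0.0603 without cervical DMSO replicate 2, and 0.074 and 0.0526 without cervical NEDD8i replicates 1 and 2. Without corneal NEDD8i replicate 1 it was 0.083 for COL5A2 and 0.0647 for TRIM22, and without cervical DMSO replicate 2 0.0717 for ESAM and 0.0561 for PLAUR. Without cervical NEDD8i replicate 1 it was 0.0622 for PLAUR and 0.0595 for KLK6, and without replicate 2 0.0524 for KLK6, 0.0514 for IL23A, 0.0518 for MUC16 and 0.0552 for CBR1. At equal depth the calls of TLR10 (0.167, value 7.0), PFKFB4 (0.496, 0.81), PSMB8 (0.0906, -2.13) and DDB2 (0.0507, -1.30) ended, without a count filter those of HMOX1 (0.133, 2.69) and KLK6 (0.0582, 3.30), and with DESeq2 that of HAS2 (0.0533, 3.63). Over all alternatives the lowest adjusted p of these 16 genes lay between 1.11e-13 for TRIM22 and 0.0131 for PFKFB4, and the highest between 0.0507 for DDB2 and 0.496 for PFKFB4. The CDH2 difference for SUMOi ended without cervical DMSO replicate 1 (0.0925) or 2 (0.0517) and without cervical SUMOi replicate 1 (0.134) or 2 (0.0946), with 3.12e-07 to 0.134 over all alternatives.

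More genes were called for NEDD8i in corneal cells (7879) than in cervical cells (5028), a ratio of 1.57. Library depth and scaling are argued against as causes, since the ratio was 1.63 with all libraries thinned to equal depth and at least 1.57 with total-count scaling or DESeq2 size factors. A spread shared by both cell types may account for the order of the counts, because separate fits turned the ratio to 0.641. A larger response of corneal cells stays open as well: genes chosen in the cervical fit alone had a corneal log2 fold change 1.16 times the cervical one by the median. Cell type, donor and culture conditions go together here, so a biological cause was not separated from them.

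SUMOi calls in corneal cells numbered 616 in the fit of 12 libraries and 10 in the fit of corneal libraries alone. Chance differences between corneal libraries are argued against as the cause of most calls, because 91.6% of them had the sign of the cervical SUMOi fold change, measured in other libraries, against 64.5% of the genes not called. The shared spread may account for the drop, since the common dispersion was 9.53 times as high in the corneal fit as in the cervical one (0.0869 and 0.00912), though the corneal fit also has fewer residual degrees of freedom and tests 13931 genes. A response to SUMOi common to both cell types is a hypothesis that stays open, and the data do not settle which of the 616 genes belong to it.

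The interferon-stimulated genes lay far higher in corneal SUMOi replicate 2 than in replicate 1, by a median of 2.34 on the log2 scale. Cells without SUMOi in replicate 1 are argued against, because over 1230 genes called for SUMOi in the cervical fit, interferon lists left out, the median response in replicate 1 was 125% of that in replicate 2 (0.936 and 0.747). So is a higher level in replicate 2 without the inhibitor, since corneal DMSO replicates 2 and 1 differed by a median of 0.073. Immune cells in replicate 2 stay open: the share of reads on their markers was 1.27 times that of replicate 1, but at 92 and 69 reads these lie too near the floor to decide. A difference between the cultures or their handling stays open too, and no biological explanation was tested because the labels do not say how the replicates differ.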

How the results depend on the processing

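Scaling by total counts, thinning to equal depth and the separate fit per cell type for the lists were alternatives chosen after the data were seen. Of the 167 gene results in the text, 166 kept direction and side of the threshold with DESeq2 size factors, 166 with replicate number as a block, 165 with DESeq2, 161 without a count filter, 161 at equal depth and 166 with total-count scaling. A stricter filter kept 164 of the 164 that it left to test, and separate fits per cell type kept 103 of 125, with 20 calls lost. Of 808 values with 1 library left out, 734 kept both and 72 lost the call, in 26 gene results. The fold moved by over 1.5 times without 1 library in 49 of 162 called gene results, and the log2 value in 14. The sign turned for NEDD8 in corneal cells with NEDD8i under total-count scaling (-0.17) and for TOP2A in corneal cells with SUMOi without corneal DMSO replicate 2 (0.27, against -1.43 without corneal SUMOi replicate 2), neither of them called. Counts within 1.5 times those reported are not repeated here.

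Separate fits gave 8498 genes for NEDD8i in cervical cells, 10 and 3638 for SUMOi in corneal and cervical cells, and 2 and 957 shared by NEDD8i and SUMOi in corneal and cervical cells. Corneal libraries varied more than cervical ones (common dispersion 0.0869 and 0.00912), which separate fits do not average. Of the genes called in the fit of 12 libraries, 5442 of 7879, 4929 of 5028, 10 of 616 and 602 of 606 were called in the same direction for NEDD8i and SUMOi in corneal and cervical cells in turn. DESeq2 gave 1157 and 951 genes for SUMOi in corneal and cervical cells, 136 for its interaction, 286 shared by NEDD8i and SUMOi in corneal cells and 381 for SUMOi in both cell types, and the cause was not tested. In the same order, no filter gave 1420, 1243, 254, 375 and 483, and 226 shared by both inhibitors in cervical cells; the cause was not tested. A block of replicate number gave 944 for SUMOi in corneal cells, 37 for its interaction, 246 and 180 shared by NEDD8i and SUMOi in corneal and cervical cells and 318 for SUMOi in both cell types. Group means subtracted, samples of 1 number correlated across genes at 0.0654, 0.403 and -0.00879 in corneal and 0.175, -0.0134 and -0.0133 in cervical cells. Highest was DMSO with SUMOi in corneal and with NEDD8i in cervical cells. Whether the numbers pair samples stays open, and why the counts rose was not tested. Equal depth, which leaves fewer reads, gave 387 for SUMOi in cervical cells, 11 for its interaction, 63 shared by NEDD8i and SUMOi in cervical cells and 128 for SUMOi in both cell types. Total-count scaling gave 3469 for the NEDD8i interaction, with the median of all genes at -0.406. With a correlation estimated per list, camera called 2 lists for NEDD8i in cervical cells (5 at an unadjusted p below 0.05) and 0 in the other 5 list tests (2 at an unadjusted p below 0.05 for NEDD8i in corneal cells, 0 elsewhere). The test fry called 0 lists for SUMOi in corneal and cervical cells and for the NEDD8i and SUMOi interactions, with 6, 4, 10 and 0 at an unadjusted p below 0.05. Camera with the preset correlation had called 6, 5, 7 and 5. The estimated correlation takes the place of the preset 0.01, and fry tests whether a list's genes move 1 way without comparing them with other genes.

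Leaving out 1 library at a time, the lone library of a group was assumed to vary like the other groups, and fewer libraries give fewer residual degrees of freedom. The counts ran from 6279 to 7917 for NEDD8i in corneal and 2643 to 2878 in cervical cells, from 308 to 646 for SUMOi in corneal and 62 to 86 in cervical cells, from 7127 to 8677 and 3875 to 4083 for NEDD8i against SUMOi, from 1008 to 2789 for the NEDD8i and 0 to 94 for the SUMOi interaction (edgeR, the 0 with 633 genes at an unadjusted p below 0.05 and 136 by DESeq2 on all libraries), and from 2154 to 4298 for corneal against cervical DMSO. Shared calls ran from 91 to 276 and 11 to 44 for both inhibitors in corneal and cervical cells, and from 2063 to 3778 and 23 to 247 for both cell types under NEDD8i and SUMOi. Lists called ran from 10 to 13 and 11 to 11 for NEDD8i, 6 to 12 and 4 to 5 for SUMOi, and 6 to 9 and 4 to 8 for the interactions. Depth sets a limit: genes below 3 counts (0.412 CPM before TMM scaling) in the shallowest library (7287801 reads) can go unseen. On simulated data (2 libraries per group) 18% to 28% of 2-fold and 78% to 86% of 4-fold changes were found.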

Other observations

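Families of barrier genes, chosen after their values were seen, were counted under both inhibitors. In corneal cells 14 of 14 late cornified envelope genes (LCE) rose (13 with total-count scaling), as did 9 of 11 small proline-rich genes (SPRR) and 11 of 11 kallikrein-related peptidases (KLK), proteases that shed the outer layer of skin. Of 12 clade B serpins (SERPINB), protease inhibitors, 8 rose. In cervical cells 2 of 14 LCE genes rose and 1 fell, 3 of 11 SPRR genes rose, with 1 falling under total-count scaling, and 9 of 11 KLK genes rose (8 with total-count scaling). Of the SERPINB genes 6 rose (5 with total-count scaling). The fit of cervical libraries alone gave 5 LCE, 6 SPRR and 9 SERPINB genes rising and 2 of each falling. With SUMOi in corneal cells 1 SPRR and 1 SERPINB gene fell, and 0 in the fit of corneal libraries alone. With SUMOi in cervical cells 5 of 11 SPRR genes and 3 of 12 SERPINB genes fell, and 11 and 8 fell in the fit of cervical libraries alone. These counts are of edgeR calls, and whether a family differed between the cell types or inhibitors was not tested as such. LCE and SPRR genes have close paralogs, and reads shared between them cannot be assigned from the counts.

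Keratins and cytoskeletal and chromatin genes, also chosen after their values were seen, went several ways under NEDD8i. Of 37 keratins, 20 rose and 5 fell in corneal cells, and 18 rose and 11 fell with total-count scaling, while 14 rose in cervical cells (12 with total-count scaling). The separate fits gave 17 keratins rising and 0 falling in corneal and 18 rising and 1 falling in cervical cells. Of 31 kinesins, motors that move along microtubules, 15 fell and 6 rose in corneal cells and 14 fell and 4 rose in cervical cells (7 rose in the cervical fit alone). Of 7 linker histone H1 genes, 4 fell and 1 rose in corneal cells (4 fell with total-count scaling) and 6 fell in cervical cells. Of 9 histone H2B genes, 6 rose in corneal cells (4 with total-count scaling and 4 in the corneal fit alone) and 1 rose in cervical cells (5 rose and 1 fell in the cervical fit alone). Of 15 S100A calcium-binding genes, 7 rose and 2 fell in corneal cells (5 and 5 with total-count scaling), and 2 rose and 6 fell in cervical cells (0 and 6 with total-count scaling, 4 and 8 in the cervical fit alone). Of 7 aldo-keto reductases (AKR1), 4 rose and 1 fell in corneal cells and 5 rose in cervical cells.

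Fibroblast markers took 0.0906% to 0.186% of reads in corneal and 0.0113% to 0.0279% in cervical libraries. The share was at most 0.00257% for immune cell markers, 0.0035% for endothelial markers and 0.0038% for melanocyte markers in any library. Genes of chromosome M took between 3.875% and 8.297% of reads per library.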
